A study of Homo sapiens with 16 samples.

How the data were processed

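Gene expression was measured by RNA sequencing of total RNA from HCT116, an established human colon cancer cell line. The 16 samples fall into 4 groups of 2 libraries, and each library has 2 sequencing runs. Per the labels' protocols, cells received either 0.5 µM of a small-molecule inhibitor of the histone methyltransferase G9a (gene symbol EHMT2), or 10 nM of a small interfering RNA (siRNA) against G9a delivered by lipid transfection, each for 72 h. Each treatment has its own control group. What the control cells received is not given in the sources used here. The series' design text speaks of biological and technical replicates. The labels' numbers were read as library and run, and the 2 runs of a library were averaged on the FPKM scale and counted once, so that n = 2 per group. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

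Libraries were made with a stranded total RNA kit and sequenced on a HiSeq-2000, per the labels' protocols. The deposited values are gene-level FPKM (fragments per kilobase of transcript and 1000000 mapped fragments) from Cufflinks, per the file headers and the submitters' processing notes. The notes also name STAR 2.3.0e as a tool, SAMtools 0.1.19 and the human build hg19. The Cufflinks version, its options, the annotation release and whether counting used the strand are not given in the sources used here. Genes that overlap, lie antisense to another gene or have near-identical copies are therefore uncertain. FPKM divides each value by a library total, so a few abundant RNAs can shift all other genes. The 6 highest values took between 48.55% and 55.76% of the summed FPKM of a run. Each file lists 63784 entries for 63653 genes, and 131 entries that repeat an identifier were summed into it. Of these genes 5903 lie on alternate or unplaced sequences. Cufflinks marked 8 genes as not reliably estimated in at least 1 run. MT-RNR2, the mitochondrial large ribosomal RNA, had that mark in all 16 runs and was left out.

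The files hold no read counts. Depth was estimated from the upper bounds of the Cufflinks confidence intervals, taking them to reflect counting error alone, which gave between 2.023 and 6.937 per run in units of 1000000 fragments. A second estimate compared genes with a single implied fragment in a pair of runs. Relative to the first run of siRNA control replicate 1, it gave depths between 0.298 and 1.016, with the shallowest runs from inhibitor control replicate 2 and siRNA control replicate 2. Low genes are least precise in those libraries.

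The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined, and those added afterwards are named as such in the closing section. Genes with a mean FPKM of at least 1 over the 8 libraries and a locus of at least 300 bases were kept, which left 12846 genes. This removed 420 shorter genes that passed the expression filter, since Cufflinks values of very short genes depend on fragment length. Libraries were scaled by median-of-ratios factors, which ranged from 0.878 to 1.091. The levels printed are these scaled FPKM, given as mean ± SD (n = 2). Differences were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend), with all 4 groups in 1 fit that shares an estimate of the spread. The fit had 4 residual degrees of freedom and 5.04 prior degrees of freedom. Fold changes are on the log2(FPKM + 1) scale with their standard error, which understates the change of low genes. The Benjamini-Hochberg threshold was 0.05, and "called" means past it. The comparisons were inhibitor against inhibitor control, siRNA against siRNA control, siRNA control against inhibitor control, and the difference between the 2 treatment effects. All tests are two-sided.

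Of 30 gene lists fixed from textbook knowledge or by a symbol rule, 27 had at least 5 measured members. The lists of germline, colonocyte and fibroblast genes had fewer and were not tested. The plan tested small structural RNAs only with short genes kept. Their result with the length filter was added to it, and both are given. Lists were tested with limma's camera at a preset correlation of 0.01 between members, and again with a correlation estimated from the data. The latter rests on 4 residual degrees of freedom. limma's fry was run beside them. It tests a list against no change, whereas camera tests it against the other genes. Its counts are of unadjusted p-values over all lists tested, so they are no counterweight to camera where many genes are called. For each list, adjusted p-values were also computed over the list alone.

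Genes were named by a rule. EHMT2 and EHMT1 came first. For each treatment, the rule then took the 10 largest increases and 10 largest decreases among called genes whose treated libraries both lay on the same side of both control libraries, with a mean of at least 2 FPKM in the higher group. Pseudogenes and symbols of clones, numbered reading frames or LOC entries were left out. From each list past the threshold it took the 4 measured members with the smallest p, and at most 3 from any other list. For the comparison of the controls and the difference of effects it took 5 in each direction. Pseudogenes were recognised from the GENCODE v29 gene type and from symbols formed from another gene's symbol, P and a number. The part on symbols was added after a first selection had shown 2 pseudogenes that the gene type missed. Some genes that this rule selected are not reported here and were left out of the named genes without replacement. Other names were chosen after their values were seen, and the text says so.

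Overlap of calls was tested with Fisher's exact test. For neighbouring genes, Spearman's correlation was computed over the log2 fold changes of adjacent tested genes at most 1000000 bases apart on the same chromosome, against 10000 shuffles of the fold changes within chromosomes. Genes are not independent replicates, so these tests describe the gene sets of these libraries. Transcript GC content and length came from the longest GENCODE v29 transcript matched by Ensembl identifier, which covered 12574 of the tested genes (97.9%). The correction removed a spline trend in both from each library. Coordinates are those of the files, counted from 1. The reference used for gene types, GC content and length is of another build, and no coordinates were taken from it.

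The fit was tested on simulated data for 12846 genes of which 200 were changed. The changed genes were drawn from those with a mean log2(FPKM + 1) of at least 2, so recovery of lower genes was not tested. For the inhibitor comparison it recovered 61.2%, 86.6% and 98.5% of genes changed by a log2 of 0.5, 1 and 2, with 13 false calls among 12646 unchanged genes. For the siRNA comparison it recovered 64.2%, 95.5% and 100%, with 10 false calls. In both, camera recovered the shifted list and called 0 of 26 others. The simulated genes varied independently, so this cannot show how camera performs on lists whose members are correlated. In the data the estimated correlation was 0.749 for the mitochondrially encoded genes. The neighbour test gave a p under 0.05 in 1 of 20 independent draws and in 5 of 5 draws with a shared component. The alternatives changed the pseudocount, the filters, the scaling, the run used, the replicate block, the groups in the fit, the prior of the spread and the distance of neighbours, and left out each library in turn. In a fit that leaves a group with a single library, that library is assumed to vary like the other groups. Data were joined and plotted with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.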

Results

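RNA from HCT116 cells, a human colon cancer line, was sequenced after G9a had been targeted in either of 2 ways. G9a (EHMT2) places methyl groups on lysine 9 of histone H3, a mark of silent chromatin, and the series asks how this mark bears on the coordination of transcription and the folding of chromosomes. The first treatment was a small-molecule inhibitor of the enzyme at 0.5 µM for 72 h, and the second was a siRNA against its messenger RNA at 10 nM for 72 h. Each had its own control group, and each of the 4 groups held 2 libraries with 2 sequencing runs. Depth implied by the deposited confidence intervals lay between 2.023 and 6.937 per run, in units of 1000000 fragments. After filtering, 12846 genes were tested.

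EHMT2 (chromosome 6, 31847536 to 31865464 in hg19) was measured first, since its level checks the labels of the siRNA libraries. It fell from 16.8 ± 1.3 FPKM in the siRNA controls to 4.61 ± 0.0996 with the siRNA (SD, n = 2), a log2 fold change of -1.67 ± 0.09 (SE, limma adjusted p = 0.000268). Both siRNA libraries, at 4.679 and 4.538, lay below all other libraries, the lowest of which was siRNA control replicate 1 at 15.93. With the inhibitor EHMT2 stood at 19.3 ± 0.517 FPKM against 22.9 ± 2.64 in the inhibitor controls, a log2 fold change of -0.23 ± 0.09 that did not pass (adjusted p = 0.0827), and against the siRNA controls it was at 0.19, in the opposite direction (adjusted p = 0.439). EHMT1 (chromosome 9, 140513444 to 140764468), which encodes the partner enzyme GLP, fell from 24.8 ± 1.04 to 11.7 ± 1.1 FPKM with the inhibitor, by 1.03 on the log2 scale (adjusted p = 0.000353). Against the siRNA controls the inhibitor libraries differed in EHMT1 by a log2 of -0.24 (adjusted p = 0.446). With the siRNA EHMT1 was at 9.62 ± 0.753 against 14 ± 2.56 FPKM, a log2 fold change of -0.49 ± 0.12 that did not pass (adjusted p = 0.0677).

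**Figure D1:**
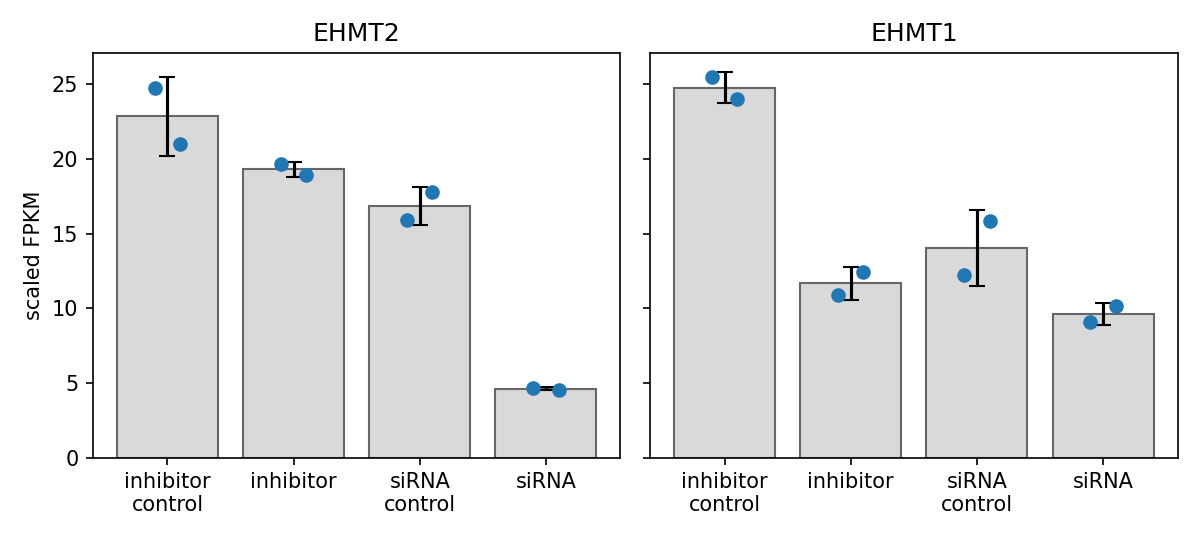
Scaled FPKM of EHMT2 and EHMT1 in the 4 groups, with bars for the mean, error bars for the SD of 2 libraries and points for the libraries. EHMT2 lies at 4.679 and 4.538 in the siRNA libraries, and EHMT1 is highest in the inhibitor control libraries, at 25.5 and 24.03.

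The 2 inhibitor control libraries stood apart from the other 6, among them the inhibitor libraries they are compared with. Across genes their log2 values correlated at r = 0.992 with each other and at 0.957 to 0.974 with the other 6, which correlated at 0.985 to 0.995 among themselves. RNA28S5, the 28S ribosomal RNA, was at 210.3 and 40.81 FPKM in the inhibitor controls and at 1045 to 18930 in the other 6. RPS16, a protein of the small ribosomal subunit, was at 462.7 and 135.3 against 8.423 to 20.25. HNRNPA2B1, an RNA-binding protein of the splicing machinery, was at 320.3 and 262.7 against 37.1 to 57.81. The nuclear long noncoding RNA MALAT1, chosen after its values were seen, was at 230.1 and 188.9 against 55.47 to 78.42. The inhibitor libraries were therefore also compared with the siRNA controls, a comparison added after this was seen. Its values are given below for the genes and lists named with the inhibitor.

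**Figure D2:**
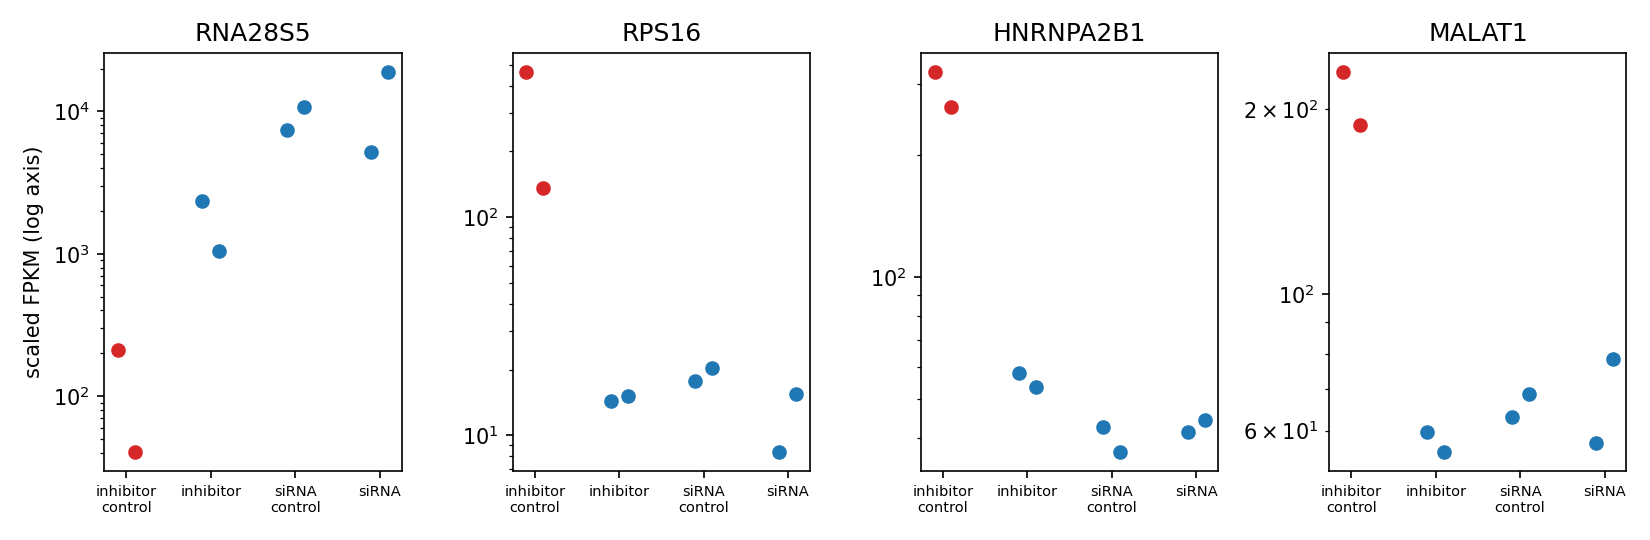
Scaled FPKM of 4 genes in each library on log axes, with the inhibitor control libraries in red and the other 6 in blue. In all 4 genes both inhibitor control libraries lie outside the range of the other 6, as for HNRNPA2B1 at 320.3 and 262.7 against 37.1 to 57.81.

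The question of the inhibitor comparison was which transcripts differ after 72 h of the inhibitor. RPS16 fell from 299 ± 232 to 14.7 ± 0.527 FPKM, a log2 fold change of -4.00 ± 0.46 (adjusted p = 0.000344). HNRNPA2B1 fell from 291 ± 40.7 to 55.7 ± 2.97 FPKM (log2 -2.36 ± 0.10, adjusted p = 3.78e-06), and its relative HNRNPH3 fell by 2.62 on the log2 scale. The linker histone gene H1F0 fell from 51.6 ± 2.99 to 9.69 ± 0.339 FPKM (log2 -2.30 ± 0.09), and FKBP5, a co-chaperone of steroid receptors, from 23.9 ± 4.53 to 3.97 ± 0.375 FPKM (log2 -2.32 ± 0.14). In the other direction RNA28S5 rose from 126 ± 120 to 1700 ± 933 FPKM (log2 4.07 ± 0.77, adjusted p = 0.00358). The other large decreases were in MT-ND3, a subunit of respiratory complex I (log2 -2.41), the mitochondrial ribosomal protein MRPL12 (-2.37), the selenium-handling enzyme SEPHS2 (-2.35), the U2 snRNP protein SNRPA1 (-2.31) and RPA1, which binds single-stranded DNA in replication (-2.25). Against the siRNA controls the inhibitor libraries were at a log2 of -0.35 for RPS16, 0.47 for HNRNPA2B1, -0.08 for HNRNPH3, 0.06 for H1F0, -0.21 for FKBP5, 0.46 for MT-ND3, -0.37 for MRPL12, 0.13 for SEPHS2, -0.34 for SNRPA1 and -0.45 for RPA1, and RNA28S5 was at -2.50. The other large increases were in BLOC1S5-TXNDC5 (1.89), SNORD3B-1 (1.76), SNHG15 (1.57), MIR3615 (1.39), FEM1A (1.20), SNORD3C (1.03) and SCARNA2 (0.98), which against the siRNA controls were at 1.11, 1.22, 0.85, -0.02, -0.41, 1.21 and -0.03. Several of these are uncertain, since BLOC1S5-TXNDC5 is a read-through of overlapping genes, MIR3615 is annotated antisense and overlaps RAB37 and SLC9A3R1, and the SNORD3 genes have near-identical copies. SNORD3B-1, SNORD3C and SCARNA2 encode small nucleolar and Cajal body RNAs.

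In all, 4686 genes (36.5%) were called with the inhibitor, 2278 higher and 2408 lower, and 288 of them by a log2 of at least 1. The share that was higher, 48.6%, was 34.8% with FPKM as deposited and 56.8% with quantile normalization. Of the 46 genes named for this comparison 45 were called. Set against the siRNA controls 5 of all genes tested passed in limma. Of the 46 named genes 0 did, with 10 at an unadjusted p under 0.05. Leaving out inhibitor replicate 2 gave 2668 called genes. The calls of BLOC1S5-TXNDC5 (adjusted p = 0.0697 without inhibitor control replicate 1, 0.0658 without inhibitor control replicate 2, 0.0994 without inhibitor replicate 1, 0.0601 without inhibitor replicate 2), SNHG15 (0.0824 without inhibitor control replicate 2, 0.0954 without inhibitor replicate 2), MIR3615 (0.0731 without inhibitor replicate 1), FEM1A (0.0718 without inhibitor replicate 2) and SNORD3C (0.0786 without inhibitor control replicate 1, 0.0602 without inhibitor replicate 1, 0.114 without inhibitor replicate 2) were lost without these libraries. With the smaller pseudocount, which stretches low values, BLOC1S5-TXNDC5 (0.00938 ± 0.000397 FPKM in the controls, 2.76 ± 0.707 with the inhibitor) was at a log2 of 4.69 and MIR3615 at 2.41. The log2 fold change was 0.48 for SNORD3C and 1.17 for SNORD3B-1 without inhibitor control replicate 1, and 1.58 for SNORD3C, 0.70 for MIR3615 and 0.67 for FEM1A without inhibitor control replicate 2. With no filter on low values the calls of RNA28S5 (adjusted p = 0.0622), SNORD3B-1 (0.0515), BLOC1S5-TXNDC5 (0.16), SNHG15 (0.131), MIR3615 (0.123), FEM1A (0.104) and SNORD3C (0.182) were lost. Robust empirical Bayes ended those of RNA28S5 (0.0553), BLOC1S5-TXNDC5 (0.0508), SNHG15 (0.1) and SNORD3C (0.123), and short genes kept ended that of SNORD3C (0.0503). With the second run alone SNORD3B-1 was at a log2 of 0.45 (adjusted p = 0.673) and SNHG15 lost its call (0.0729), as did BLOC1S5-TXNDC5 with the first run alone (0.172).

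Among the gene lists, the transcripts of the mitochondrial genome fell with the inhibitor, with 0 members higher, 11 lower and 1 not called of 12 (median log2 -1.48, camera adjusted p = 2.75e-07; 11 lower when adjusted over the list alone). The list's call was lost with adjusted p = 0.444 with an estimated correlation. MT-ND3 fell from 717 ± 105 to 134 ± 12.2 FPKM and MT-ATP6, a subunit of ATP synthase, from 763 ± 147 to 172 ± 26.9. MT-ND1 and MT-CO2 fell too (log2 -1.84 and -1.67). Against the siRNA controls the median of the list was 0.275, in the opposite direction, with MT-ND3, MT-ATP6, MT-ND1 and MT-CO2 at 0.46, 0.37, 0.27 and 0.19. That shift passed in camera (adjusted p = 0.000174), but not with an estimated correlation (adjusted p = 0.451). The nuclear-encoded subunits of the respiratory chain had 40 higher, 10 lower and 30 not called of 80 (median log2 0.20, adjusted p = 0.000444; 42 and 12 over the list alone, and adjusted p = 0.444 with an estimated correlation). Of the 4 members with the smallest p, UQCRQ of complex III rose by a log2 of 0.54, while NDUFA8 (-1.13), NDUFS6 (-0.68) and ATP5J (-0.68) fell. Against the siRNA controls the median was -0.04 and these members were at -0.08, -0.04, -0.01 and 0.01. That opposite shift passed in camera (adjusted p = 0.036), but not with an estimated correlation (adjusted p = 0.621). With no filter on low values the list's median against the inhibitor controls was 0.109.

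Replication-dependent histone genes, which supply histones during DNA synthesis, had 33 higher, 6 lower and 17 not called of 56 with the inhibitor (median log2 0.30, adjusted p = 1.41e-05; 38 and 6 adjusted over the list alone; adjusted p = 0.5 with an estimated correlation). HIST3H2A rose from 57.7 ± 2.11 to 108 ± 7.33 FPKM, HIST3H2BB and HIST2H2AC rose by a log2 of 0.43 and 0.45, and HIST1H4E fell by 0.71. Members of this family share near-identical coding sequence. The median against the siRNA controls was -0.09, with HIST3H2A, HIST3H2BB, HIST2H2AC and HIST1H4E at -0.14, 0.01, -0.05 and -0.09. That opposite shift passed in camera (adjusted p = 4.78e-06), but not with an estimated correlation (adjusted p = 0.451). With no filter on low values the list's median against the inhibitor controls was 0.19. Cytosolic ribosomal protein genes had 47 higher, 14 lower and 18 not called of 79 (median log2 0.21, adjusted p = 0.000339), a call that ended with quantile normalization (median 0.093, adjusted p = 0.434; 2.09e-05 to 0.642 over the alternatives) and with an estimated correlation (adjusted p = 0.642). Adjusted over the list alone, 49 were higher and 14 lower. The 4 members with the smallest p all fell, against the direction of the list. They were RPL28 (399 ± 30.3 to 87.3 ± 1.01 FPKM), RPL8, RPS21 and RPS2, with log2 fold changes of -2.18, -1.35, -1.29 and -0.98. The median against the siRNA controls was 0.02 and these members were at 0.20, -0.07, 0.15 and 0.08.

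The list of H3K9 methylation writers, readers and erasers, which holds EHMT2 and EHMT1, had 3 higher, 14 lower and 11 not called of 28 with the inhibitor (median log2 -0.35, adjusted p = 0.0104). Over the list alone 3 were higher and 15 lower, and with an estimated correlation the camera adjusted p was 0.365. UHRF1, which links H3K9 methylation to DNA methylation, fell from 38.3 ± 3.85 to 20.4 ± 0.572 FPKM. CBX5, which encodes the reader HP1 alpha, and MPHOSPH8, a reader in the HUSH silencing complex, fell as well (log2 -0.97 and -1.11). The median against the siRNA controls was 0.03, with UHRF1 at -0.07, CBX5 at -0.08 and MPHOSPH8 at 0.15. Heat shock genes had 2 higher, 9 lower and 3 not called of 14 (median log2 -0.215, adjusted p = 0.00726; 2 and 9 over the list alone; adjusted p = 0.365 with an estimated correlation). The cytosolic chaperone HSP90AA1 fell from 430 ± 101 to 162 ± 7.75 FPKM and the small heat shock protein HSPB1 from 133 ± 8.47 to 56.6 ± 1.87, as did the co-chaperones CHORDC1 and BAG3 (log2 -1.03 and -1.07). Genes of MYC and ribosome biogenesis had 3 higher, 11 lower and 7 not called of 21 (median log2 -0.15, adjusted p = 0.0107; 3 and 12 over the list alone; adjusted p = 0.444 with an estimated correlation). Nucleolin (NCL) fell from 480 ± 3.34 to 119 ± 5.38 FPKM, the pyrimidine synthesis enzyme CAD from 29.3 ± 2.11 to 13.1 ± 0.895, and the nucleolar proteins FBL and NOLC1 fell as well (log2 -1.54 and -1.01). Against the siRNA controls the medians of the heat shock and MYC lists were -0.08 and -0.03, with adjusted p = 0.169 and 0.26. In that comparison HSP90AA1, HSPB1, CHORDC1 and BAG3 were at -0.30, -0.02, -0.11 and -0.15, and NCL, CAD, FBL and NOLC1 at 0.04, -0.25, -0.07 and 0.03. Over all alternatives the adjusted p ranged from 0.000312 to 0.365 for heat shock and from 0.000522 to 0.444 for MYC.

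The other lists did not pass with the inhibitor when the length filter was used. Interferon-stimulated genes had 5 higher and 1 lower of 16 (median log2 0.18, adjusted p = 0.135) and p53 targets 3 and 5 of 21 (0.02, adjusted p = 0.772). Imprinted genes had 2 and 4 of 13 (-0.21, adjusted p = 0.128) and zinc finger genes of chromosome 19 had 12 and 5 of 105 (0.10, adjusted p = 0.135). Over the list alone the counts were 5 and 1, 3 and 6, 2 and 6, and 5 and 3. The medians of these lists against the siRNA controls were 0.116, 0.09, -0.003 and -0.06 (adjusted p = 0.0268, 0.0695, 0.868 and 0.035). The interferon and zinc finger lists lost this call with adjusted p = 0.451 and 0.264 with an estimated correlation. Small structural RNAs had 8 higher and 2 lower of 28 with the inhibitor (camera adjusted p = 0.0711). With short genes kept, as planned for this list, 31 were higher and 7 lower of 258 (median log2 0.344). That passed in camera (adjusted p = 0.00584), but not with an estimated correlation (adjusted p = 0.424). In all, 7 of 27 lists passed with the length filter. With an estimated correlation 0 did in camera, with 2 at an unadjusted p under 0.05. In fry, which tests against no change, 20 had an unadjusted p under 0.05. Leaving out inhibitor replicate 1 gave 11 lists. With the siRNA controls as the reference 9 lists passed, and 0 with an estimated correlation in camera (4 at an unadjusted p under 0.05, and 6 in fry), and 4 of the 7 had medians of the opposite sign.

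The siRNA comparison asked which transcripts differ 72 h after the knockdown. Apart from EHMT2, TPM2, which encodes a tropomyosin of actin filaments, fell from 121 ± 2.09 to 67.7 ± 3.21 FPKM (log2 -0.83 ± 0.05, adjusted p = 0.000504), and the metallothionein MT2A, which binds metal ions, from 130 ± 8.58 to 75.9 ± 2.87 (log2 -0.77 ± 0.07, adjusted p = 0.00351). FGFBP1, a secreted carrier of fibroblast growth factors (chromosome 4, 15937192 to 15940363), rose from 15.7 ± 1.01 to 25.8 ± 1.51 FPKM (log2 0.69 ± 0.07, adjusted p = 0.00655). ANKRD10-IT1, a transcript within an intron of ANKRD10 and so uncertain, rose from 3.78 ± 0.629 to 10.5 ± 1.24 FPKM (log2 1.27 ± 0.12). ACSL5, which activates long-chain fatty acids, rose from 1.38 ± 0.071 to 3.73 ± 0.378 FPKM (log2 0.99 ± 0.14, adjusted p = 0.0222). The other large increases were in SNHG7 (0.84), which is antisense and so uncertain, PLEKHA4 (0.82), TMEM14A (0.71), the nicotinamide riboside kinase NMRK1 (0.70), the translocon subunit SEC61G (0.69), the sulfide-oxidising enzyme SQRDL (0.65) and SH3TC2 (0.64). The other large decreases were in BCL2L12 (14.1 ± 2.42 to 6.03 ± 0.89 FPKM), SNHG9 (log2 -0.93), BANF1 (-0.84), which bridges chromatin and the nuclear envelope, MRFAP1 (-0.71), PGD (-0.69) of the pentose phosphate pathway, the splicing factor SF3A1 (-0.69) and the cell cycle transcription factor MYBL2 (-0.68).

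With the siRNA 273 genes (2.1%) were called, 103 higher and 170 lower, and 11 of them by a log2 of at least 1. The share that was higher, 37.7%, was 14.9% with FPKM as deposited and 49.1% with quantile normalization. Within its group siRNA control replicate 2 stood apart, at 0.859 on the second principal component (12.4% of the variance), where the other 7 libraries lay between -0.33 and 0.143. The number of calls was 8 without siRNA control replicate 2 and 424 without siRNA control replicate 1. It was 26 and 66 without siRNA replicates 1 and 2, 49 and 58 without inhibitor replicates 1 and 2, and 148 and 145 without inhibitor control replicates 1 and 2, which enter the estimate of the spread. Of the 37 genes named for this comparison 31 were called, and EHMT2, TPM2, MT2A, FGFBP1 and ANKRD10-IT1 kept their call whichever library was left out. Of these, ANKRD10-IT1, FGFBP1 and MT2A lost it with no filter on low values (adjusted p = 0.0841, 0.0725 and 0.0725), and ANKRD10-IT1 also with the first run alone (0.0593). Among the named genes the number of calls lost was 25 without siRNA control replicate 2, 5 without siRNA control replicate 1, 26 and 17 without siRNA replicates 1 and 2, 16 without either inhibitor library and 8 without either inhibitor control library. ACSL5 was then at adjusted p = 0.144 without siRNA control replicate 2 and at 0.0996 and 0.0765 without siRNA replicates 1 and 2. BCL2L12 was at 0.187 without siRNA control replicate 2, at 0.134 and 0.0571 without siRNA replicates 1 and 2, and at 0.0504 and 0.05 without inhibitor replicates 1 and 2. SNHG9 was at a log2 of -0.59 without siRNA control replicate 1. Of the named genes 29 lost the call with no filter on low values, 25 with short genes kept, 24 in a fit of the compared groups alone, 21 and 19 with the first and the second run alone, 11 with FPKM as deposited, 5 with quantile normalization, and 2 each with the smaller pseudocount and robust empirical Bayes. The replicate number as a block ended the call of 14 of the named genes. SH3TC2 was at a log2 of 0.38 with the first run alone.

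Among the lists, cytosolic ribosomal protein genes had 4 higher, 1 lower and 74 not called of 79 with the siRNA (median log2 0.11, camera adjusted p = 2.2e-06), and with quantile normalization the median was -0.015 and the call ended (adjusted p = 0.804; 6.83e-08 to 0.804 over the alternatives). The median was 0.05 with FPKM as deposited and 0.055 without siRNA control replicate 2, the library that stands apart in its group. Adjusted over the list alone 25 were higher and 4 lower, and the list had adjusted p = 0.661 with an estimated correlation. RPL37 rose from 773 ± 27.3 to 960 ± 24.1 FPKM, RPL10 and RPS27L rose by a log2 of 0.30 and 0.51, and RPL8 fell from 661 ± 26.4 to 502 ± 22.3 FPKM. With quantile normalization RPL10 was at 0.16 and lost its call (adjusted p = 0.0633). Genes of MYC and ribosome biogenesis had 0 higher, 3 lower and 18 not called of 21 (median log2 -0.12, adjusted p = 0.00262; 7 lower over the list alone; adjusted p = 0.411 with an estimated correlation). NCL fell from 115 ± 5.64 to 77 ± 15.4 FPKM, and NOLC1 and NOP56 fell too (log2 -0.37 and -0.25), while NOP16 at -0.25 did not pass. Without siRNA replicate 1 NCL was at -0.39 (adjusted p = 0.108). Zinc finger genes of chromosome 19 had 0 higher, 3 lower and 102 not called of 105 (median log2 -0.10, adjusted p = 0.00262; 3 lower over the list alone; adjusted p = 0.18 with an estimated correlation). ZNF776 fell from 5.79 ± 0.143 to 3.53 ± 0.0568 FPKM, ZNF581 and ZNF551 fell too (log2 -0.53 and -0.42), and ZNF714 was at -0.27 without passing. With a mean FPKM of at least 5 the list's call was lost (adjusted p = 0.119), and with no filter on low values its median was -0.018.

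Small structural RNAs had 1 higher, 0 lower and 27 not called of 28 with the siRNA (median log2 0.30, adjusted p = 0.00673; 3 higher and 2 lower over the list alone; adjusted p = 0.481 with an estimated correlation), and with quantile normalization the median was 0.13 and the call ended (adjusted p = 0.2; 4.9e-05 to 0.985 over the alternatives). RPPH1, the RNA of ribonuclease P, which overlaps PARP2 and so is uncertain, rose from 21300 ± 694 to 32700 ± 1430 FPKM. With quantile normalization it was at a log2 of 0.00. That scaling gives equal values to a gene with the same rank in all libraries. It therefore cannot show a change of such a highly abundant RNA. The list's call was also lost with no filter on low values (median 0.00, adjusted p = 0.985), with a mean FPKM of at least 5 (0.069) and with the second run alone (0.0566). With short genes kept, as planned for this list, 2 were higher and 0 lower of 258 (median log2 0.265). That passed in camera (adjusted p = 0.00172), but not with an estimated correlation (adjusted p = 0.525). SNORD3A (0.99) and the 7SK-derived copies RN7SKP180 (0.91) and RN7SKP48 (-0.66), which share reads with near-identical genes, did not pass. The 4 lists lost their call with an estimated correlation, where 0 passed in camera, with 1 at an unadjusted p under 0.05, while fry gave 9 under 0.05. Without siRNA control replicate 1 only the list of cytosolic ribosomal proteins passed, and the lists of MYC and ribosome biogenesis, zinc finger genes and small structural RNAs were at adjusted p = 0.117, 0.121 and 0.44. Over their alternatives the lists of MYC and ribosome biogenesis and of zinc finger genes ranged from adjusted p = 7.25e-05 to 0.411 and from 0.000133 to 0.18. The H3K9 machinery had 0 higher and 2 lower of 28 with the siRNA (median log2 -0.07, camera adjusted p = 0.0978). The 2 lower members were EHMT2 itself and UHRF1, and over the list alone 3 were lower.

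**Figure D3:**
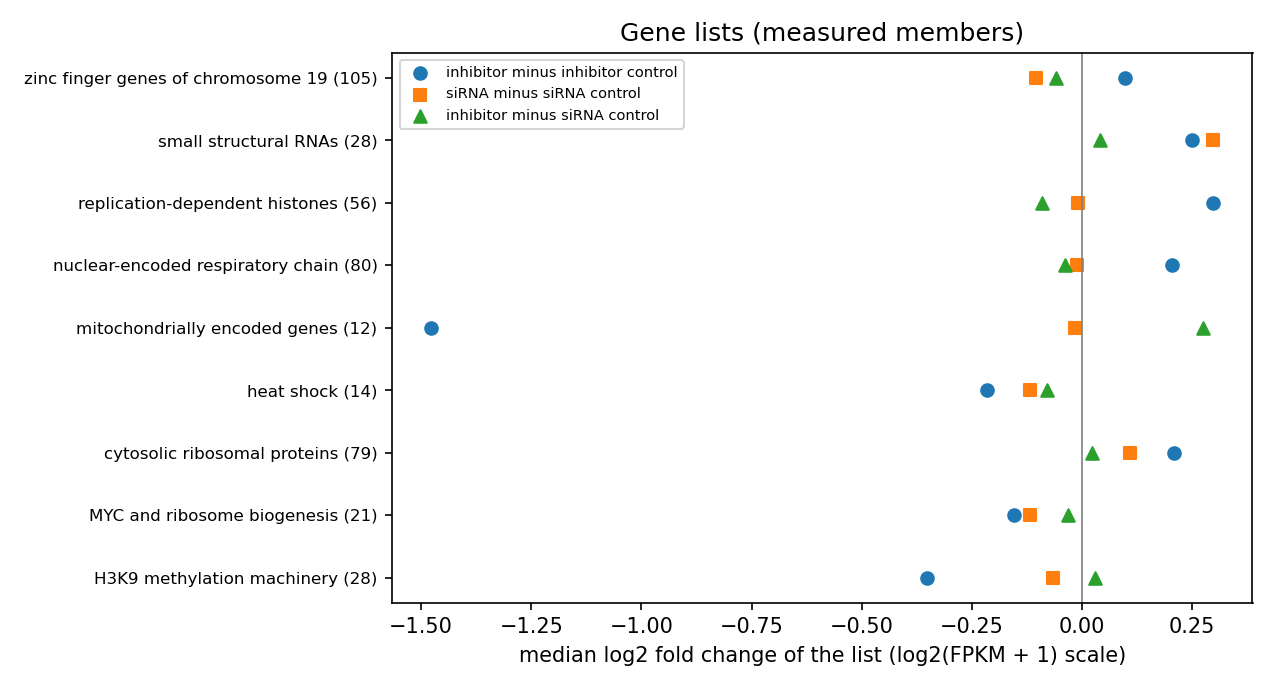
Median log2 fold change of 9 gene lists (horizontal axis, log2(FPKM + 1) scale) in 3 comparisons, with the number of measured members in brackets. The mitochondrially encoded genes lie at -1.48 for inhibitor against inhibitor control and at 0.275 for inhibitor against siRNA control. The cytosolic ribosomal proteins lie at 0.11 for the siRNA. Their median of -0.015 with quantile normalization is not drawn.

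The control groups were compared with each other to give the background between the 2 experiments. RNA28S5 was higher in the siRNA controls than in the inhibitor controls, at 9080 ± 2430 against 126 ± 120 FPKM (log2 6.57 ± 0.77, adjusted p = 0.000329). HIST2H2AA3 was higher too, at 13.2 ± 5.39 FPKM (adjusted p = 0.00123), and HIST2H4B and FEM1A were higher by a log2 of 1.63 and 1.62. The histone genes have near-identical copies. Lower in the siRNA controls were RPS16 at 19 ± 1.78 against 299 ± 232 FPKM (log2 -3.66), HNRNPA2B1 at 39.9 ± 3.95 against 291 ± 40.7 (log2 -2.83), MT-ND3 (-2.87), the Cajal body RNA SCARNA9 (-2.77), which overlaps KIAA1731 and is uncertain, and HNRNPH3 (-2.55). In all 4916 genes were called, 2472 higher and 2444 lower, and 359 by a log2 of at least 1. The share that was higher, 50.3%, was 18% with FPKM as deposited, which moved the median of all genes to -0.11, and 55.8% with quantile normalization.

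The mitochondrially encoded genes had 0 higher and 12 lower of 12 in the siRNA controls (median log2 -1.765, adjusted p = 9.36e-09), histone genes 40 higher and 5 lower of 56 (0.405, adjusted p = 2.24e-08), and the nuclear respiratory chain 47 and 8 of 80 (0.24, adjusted p = 4.37e-06). Over the list alone these counts were 12 lower, 43 and 7, and 50 and 10. With an estimated correlation the adjusted p-values of these lists were 0.381, 0.403 and 0.381. Cytosolic ribosomal proteins had 39 higher and 15 lower of 79, with a median log2 of 0.16 and a mean of -0.01 that differs in sign (adjusted p = 0.00961; adjusted p = 0.681 with an estimated correlation). The H3K9 machinery had 2 higher and 14 lower of 28 (-0.31, adjusted p = 0.00958), zinc finger genes of chromosome 19 had 20 and 3 of 105 (0.16, adjusted p = 0.011), heat shock genes 2 and 7 of 14 (-0.19, adjusted p = 0.0237), epithelial markers 1 and 6 of 16 (-0.295, adjusted p = 0.0237), fatty acid synthesis 1 and 7 of 13 (-0.43, adjusted p = 0.0239), immediate early genes 2 and 6 of 16 (-0.26, adjusted p = 0.0239) and MYC and ribosome biogenesis 4 and 9 of 21 (-0.09, adjusted p = 0.0352). Over the list alone these counts were 2 and 15, 12 and 2, 2 and 8, 1 and 6, 1 and 8, 2 and 6, and 4 and 9. The inhibitor control libraries that stand apart are one side of each of these differences. In all 11 of 27 lists passed, and 0 did with an estimated correlation in camera, with 4 at an unadjusted p under 0.05, while fry gave 19 under 0.05. This comparison and the inhibitor comparison share the inhibitor control libraries, so their likeness was not counted.

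The effects of the inhibitor and the siRNA were compared directly as the difference of their log2 fold changes. EHMT2 differed by 1.44 ± 0.13 (adjusted p = 0.000776), being lower with the siRNA. RNA28S5 differed by 3.91 ± 1.09, FEM1A by 1.69 ± 0.40, HIST2H2AA3 by 1.46 ± 0.33 and MTRNR2L10, a nuclear gene that resembles the mitochondrial large ribosomal RNA and so is uncertain, by 1.64 ± 0.29. RPS16 (-3.32), HNRNPH3 (-2.58), SEPHS2 (-2.47), HNRNPA2B1 (-2.47) and SDHC (-2.40), a subunit of respiratory complex II, differed in the other direction. In all 1520 genes were called, 663 with the higher and 857 with the lower value for the inhibitor. The share that was higher, 43.6%, was 32.8% with FPKM as deposited. The count was 488 and 587 without inhibitor replicates 2 and 1, 796 and 944 without inhibitor control replicates 1 and 2, and 625 without siRNA replicate 2. RNA28S5 lost its call without inhibitor control replicate 2 (adjusted p = 0.101), inhibitor replicates 1 and 2 (0.144 and 0.079), siRNA control replicates 1 and 2 (0.0885 and 0.124) or siRNA replicate 1 (0.11). FEM1A lost it without inhibitor replicates 1 and 2 (0.0663 and 0.105), siRNA control replicates 1 and 2 (0.0631 and 0.0818) or siRNA replicate 2 (0.107). HIST2H2AA3 lost it without inhibitor control replicate 1 (0.0709), inhibitor replicates 1 and 2 (0.0636 and 0.0895) or siRNA replicate 2 (0.0905), and RPS16 without inhibitor replicates 1 and 2 (0.0531 and 0.0557) or siRNA replicate 2 (0.0593). With no filter on low values RNA28S5 (0.27), FEM1A (0.189), MTRNR2L10 (0.104), HIST2H2AA3 (0.169), RPS16 (0.143), HNRNPH3 (0.105) and SDHC (0.0638) lost their call. RNA28S5 also lost it with the smaller pseudocount, short genes kept, either run alone or robust empirical Bayes (0.052 to 0.213), FEM1A and HIST2H2AA3 with short genes kept (0.0635 and 0.054) or the first run alone (0.0907 and 0.0546), and RPS16 with robust empirical Bayes (0.0986).

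The mitochondrially encoded genes had 0 higher and 9 lower of 12 for the difference of effects (median log2 -1.47, adjusted p = 7.4e-10; adjusted p = 0.377 with an estimated correlation), histone genes 15 and 2 of 56 (0.21, adjusted p = 8e-06; 0.565) and the nuclear respiratory chain 21 and 4 of 80 (0.19, adjusted p = 5.34e-05; 0.48). Zinc finger genes of chromosome 19 had 8 higher and 1 lower of 105 (0.20, adjusted p = 0.000355; 0.121), epithelial markers 0 and 1 of 16 (-0.215, adjusted p = 0.0309; 0.377) and heat shock genes 0 and 4 of 14 (-0.09, adjusted p = 0.0309; 0.377). Over the list alone the counts were 12 lower, 26 and 4, 33 and 6, 2 and 0, 1 lower, and 2 and 4. These lists too rest on the inhibitor control libraries that stand apart.

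FGFBP1 is among the genes called with both treatments, at 25 ± 0.946 FPKM with the inhibitor against 14.4 ± 0.27 in its controls (log2 0.76 ± 0.07) and with a log2 fold change of 0.69 ± 0.07 with the siRNA. It was also higher in the inhibitor libraries than in the siRNA controls (log2 0.64, adjusted p = 0.0274). NCL, NOLC1, BANF1, MYBL2 and PGD fell with both treatments, at a log2 of -2.00, -1.01, -2.20, -1.15 and -1.34 with the inhibitor against its own controls. Their siRNA calls were all lost with no filter on low values (limma adjusted p = 0.137 to 0.214). The same held in a fit of the compared groups alone (0.0623 to 0.0997). Set against the siRNA controls, the inhibitor libraries were at 0.04, 0.03, -0.13, -0.32 and -0.27 for these genes, and none passed. The 2 comparisons use no library in common, although they share the estimate of the spread. In all 188 genes were called in the same direction, 72 higher and 116 lower in both, where independent lists would share 18.3 and 31.9. Fisher's exact test gave p = 1.93e-31 and p = 1.01e-45, across genes that are not independent. Another 16 genes were called in opposite directions against 49.5 for independent lists. Across all genes the fold changes correlated at Pearson's r = 0.302 and Spearman's rho = 0.357. The shared calls numbered 7 without siRNA control replicate 2, 14 and 57 without siRNA replicates 1 and 2, 29 and 33 without inhibitor replicates 1 and 2, and 84 and 94 without inhibitor control replicates 1 and 2.

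The title of the series speaks of coordinated transcription, so the fold changes of neighbouring genes were compared. Over 9826 pairs of adjacent genes Spearman's rho was 0.073 with the inhibitor and 0.089 with the siRNA. Shuffling the values within chromosomes gave means of 0.016 and 0.018 and a permutation p of 0.0001 for both, the smallest that 10000 shuffles can give. As background, the difference between the 2 libraries of a group gave rho = 0.091 for the siRNA controls (permutation p = 0.0001), 0.029 for the inhibitor controls (permutation p = 0.0329), 0.018 for the inhibitor (permutation p = 0.153) and 0.009 for the siRNA (permutation p = 0.511). The value for the siRNA controls alone is as large as that of the siRNA comparison, whose rho was 0.059 without siRNA control replicate 2, the library that stands apart in its group. With the siRNA controls as the reference rho with the inhibitor was 0.029 (permutation p = 0.0174). With no filter on low values it was 0.042 with the inhibitor (permutation p = 0.0001) and 0.036 with the siRNA (permutation p = 0.0003). With values corrected for GC content and length, an alternative added after the data were seen, rho was 0.000 with the inhibitor (permutation p = 0.907) and 0.044 with the siRNA (permutation p = 0.0002).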

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

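The tests of explanations in this part were chosen after the result was seen. The inhibitor and the siRNA are aimed at the same enzyme, and results are given here because a direct test of the difference between their effects passed. The difference of log2 fold changes, inhibitor minus siRNA, passed for 1520 genes. Among the named genes it was 3.91 for RNA28S5, 1.69 for FEM1A, 1.64 for MTRNR2L10, 1.46 for HIST2H2AA3 and 1.44 for EHMT2, and -3.32 for RPS16, -2.58 for HNRNPH3, -2.47 for SEPHS2, -2.47 for HNRNPA2B1 and -2.40 for SDHC. Among the lists the median difference was -1.47 for the mitochondrially encoded genes, 0.21 for replication-dependent histones, 0.19 for the nuclear-encoded respiratory chain, 0.20 for zinc finger genes of chromosome 19, -0.21 for epithelial markers and -0.09 for heat shock genes. With an estimated correlation 0 of these lists passed in camera, with 3 at an unadjusted p under 0.05. In fry, which tests against no change, 14 of all 27 lists had an unadjusted p under 0.05. EHMT2 was at -1.67 with the siRNA and -0.23 with the inhibitor, each against its own controls. The medians with the siRNA and the inhibitor were -0.104 and 0.097 for zinc finger genes and 0.131 and -0.145 for epithelial markers. Against the siRNA controls, the inhibitor medians of these lists were -0.06 and 0.072, in the same direction as with the siRNA. Their opposite signs thus appear only with the inhibitor controls as the reference. The difference for EHMT2 does not rest on the inhibitor comparison alone. All the genes and lists named here also passed between the 2 control groups, where the inhibitor control libraries stand apart from the other 6.

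The inhibitor itself is a biological explanation for that pattern, since the inhibitor comparison rests on those controls. Over the 4686 genes called with the inhibitor, the inhibitor libraries differed from their own controls by a median log2 of 0.421 in the direction of the call, and from the siRNA controls by 0.028 (quartiles -0.058 to 0.117), which argues against the inhibitor as the main source if, as their group name implies, the siRNA controls had none. Bias by GC content or length is argued against as the whole source, since 4371 genes were still called with the correction. A library preparation or removal of ribosomal RNA that differed for the inhibitor controls may be a source. RNA28S5 was at least 4.97 times higher in each of the other 6 libraries. It also varied widely within groups, at 210.3 and 40.81 FPKM in the inhibitor controls and 5174 and 18930 with the siRNA. No label gives a preparation batch, so preparation and control group cannot be told apart. A difference in the state of the control cells also stays open, as untested.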

How the results depend on the processing

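Of the alternatives used here, the siRNA controls as the reference, the correction for GC content and length and the fits without the inhibitor controls were chosen after the data were seen. The fall of EHMT2 with the siRNA kept its direction and call in every alternative run, from -1.741 to -1.597 when 1 library was left out. The cause was not tested for any change below unless the setting itself has fewer genes, libraries or runs.

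With no filter on low values 2996 genes were called with the inhibitor, 5 with the siRNA, 3175 between the controls, 239 for the difference of effects and 2 in both treatments, and 14 lists with the inhibitor. With a mean FPKM of at least 5, which tests fewer genes, the siRNA gave 587 genes and 2 lists, and 411 genes were shared. With short genes kept the siRNA gave 22 genes and 14 were shared. With FPKM as deposited the counts were 3112 for the inhibitor, 134 for the siRNA, 738 for the difference and 78 shared. The first sequencing run alone gave 3117, 31, 3212 for the controls, 526 and 19, and the second run alone 45 for the siRNA, 717 for the difference and 27 shared. A fit of the compared groups alone gave 24 siRNA genes. With a log2 fold change of at least 1 also required, 288, 11, 359 and 241 genes passed for inhibitor, siRNA, controls and difference, and 1 was shared. With an estimated correlation 0 lists passed in either treatment. Without the 2 inhibitor control libraries the siRNA gave 151 genes. With GC and length corrected the rho of neighbours with the inhibitor was 0.000.

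No shared deviation of like-numbered libraries was seen, with correlations of -0.098 to 0.048 between groups. Noise of single libraries could hide one, so a pairing cannot be excluded. With the replicate number as a block 68 siRNA genes were called, 67 of them also called without it, and 50 were shared by both treatments. The block ended the calls of 14 genes named for the siRNA, SNHG7, NMRK1, SEC61G, SH3TC2, PGD, MYBL2, NOP56, RPL37, RPS27L, RPL10, RPPH1, ZNF776, ZNF581 and ZNF551 (adjusted p = 0.0522 to 0.0797), and that of RNA28S5 for the difference of effects (0.0659), and no other call of a named gene or list. The block together with the correction for GC content and length gave 129 siRNA genes.

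Leaving out 1 library in turn gave 2668 to 4770 genes for the inhibitor, 8 to 424 for the siRNA, 3439 to 4846 between the controls, 488 to 1461 for the difference and 7 to 268 shared. Lists numbered 7 to 11 with the inhibitor and 1 to 6 with the siRNA, and the rho of neighbours was 0.051 to 0.090 and 0.059 to 0.106. Of the 45 called genes named for the inhibitor 38 kept their call in all alternatives fixed beforehand other than the fold threshold, of the 31 for the siRNA only EHMT2 and TPM2, of the 10 for the difference of effects 3, and all 9 for the controls. TPM2 and some of the 38 do not reach a log2 of 1. No list kept its call in all of them, since none passed with an estimated correlation. At the preset correlation 6 of 7 with the inhibitor and 0 of 4 with the siRNA kept it in all that were fixed beforehand.

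With the siRNA controls as the reference 5 genes were called with the inhibitor, and the direction turned for 4 lists, with medians of 0.029 for the H3K9 machinery, 0.275 for mitochondrially encoded genes, -0.039 for the nuclear respiratory chain and -0.091 for histones. It turned for 21 named genes that had been called: RNA28S5 (-2.50), MIR3615 (-0.02), FEM1A (-0.41), SCARNA2 (-0.03), MT-ND3 (0.46), HNRNPA2B1 (0.47), SEPHS2 (0.13), H1F0 (0.06), MPHOSPH8 (0.15), NCL (0.04), NOLC1 (0.03), RPL28 (0.20), RPS21 (0.15), RPS2 (0.08), MT-ND1 (0.27), MT-CO2 (0.19), MT-ATP6 (0.37), ATP5J (0.01), UQCRQ (-0.08), HIST3H2A (-0.14) and HIST2H2AC (-0.05). EHMT2, which was not called with the inhibitor, also changed sign, from -0.23 to 0.19. With quantile normalization the median of cytosolic ribosomal proteins with the siRNA turned to -0.015. Depth limits low genes most, and the shallowest libraries, inhibitor control replicate 2 and siRNA control replicate 2, are at a relative depth near 0.30.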

Other observations

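Of the tests of explanations in this part, the correlation with the correction for GC content and length, the correlation with divided controls and the neighbours from different library pairs were set before their results were seen, and all others, with the comparison of inhibitor and siRNA control libraries, were chosen afterwards. In that comparison 5 genes passed in limma, with 1599 at an unadjusted p under 0.05, and they are named after their values were seen. FGFBP1, a carrier of fibroblast growth factors, was higher with the inhibitor by a log2 of 0.64 ± 0.07, S100A4, a calcium-binding protein of motile cells, by 0.65 ± 0.06 (76.3 ± 2.16 against 48.2 ± 1.39 FPKM) and KIAA0101, a partner of the replication clamp, by 0.78 ± 0.07 (72.4 ± 2.16 against 41.8 ± 3.12 FPKM). FGFBP1 and S100A4 were higher than in the inhibitor controls too, by 0.76 and 0.48, and KIAA0101 by 0.28. The transcripts ANKRD10-IT1 (1.19) and AC009133.15 (-2.66) lie within or antisense to other genes and are uncertain. FGFBP1, KIAA0101 and ANKRD10-IT1 were also higher in the siRNA libraries than in the siRNA controls (log2 0.69, 0.63 and 1.27). The same siRNA control libraries are thus one side of both differences.

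In the same comparison 9 lists passed in camera and 0 with an estimated correlation, and no member was called over all genes. Replication-dependent histones had the smallest adjusted p (median log2 -0.09, camera adjusted p = 4.78e-06). Mitochondrially encoded genes (0.275, adjusted p = 0.000174) and the nuclear respiratory chain (-0.039, adjusted p = 0.036) passed too. These lists all went against their direction with the inhibitor controls as the reference. Genes of cholesterol synthesis and uptake were higher with the inhibitor than in the siRNA controls (median log2 0.09 over 22 members, adjusted p = 2.5e-05; 4 higher adjusted over the list alone; adjusted p = 0.266 with an estimated correlation). IDI1, an isomerase of isoprenoid synthesis (0.25 ± 0.06), and FDFT1, the squalene synthase (0.19 ± 0.05), were among the members with the smallest p, but against the inhibitor controls FDFT1 was at -0.097 and the list's median at -0.08. Targets of NRF2, the regulator of the oxidative stress response, were lower (median log2 -0.13 over 14 members, adjusted p = 0.00438; 4 lower over the list alone; adjusted p = 0.264 with an estimated correlation). FTL, the light chain of ferritin, was at 1363 ± 34.1 against 1823 ± 15.8 FPKM (log2 -0.42 ± 0.05), NQO1 at -0.25 ± 0.04 and HMOX1 at -0.37 ± 0.09. Against the inhibitor controls the list's median was 0.087, in the opposite direction, and NQO1 was at 0.36. Interferon-stimulated genes had a median of 0.12 over 16 members (adjusted p = 0.0268; 1 higher over the list alone; adjusted p = 0.451 with an estimated correlation) and epithelial markers 0.07 over 16 (adjusted p = 0.0105; 3 higher over the list alone; adjusted p = 0.264 with an estimated correlation). Against the inhibitor controls the interferon list was at 0.179 and the epithelial markers at -0.145, the latter in the opposite direction with 1 member higher and 5 lower. The labels do not say what the control cells received, so treatment and handling cannot be separated here.

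The fold changes of the inhibitor and the siRNA go together across genes although the comparisons share no library. A trend with GC content or length in both is argued against as the whole source, since the correlation was 0.312 before the correction and 0.29 with it on 12574 genes. Lower activity or level of the targeted enzyme in both could give this pattern. With the siRNA controls divided, 1 for each treatment, the correlation was 0.222 and 0.136, below the 0.302 against their own controls and above 0, so the test leaves this open, as single libraries also add noise. The first principal component (62.4% of the variance) set the inhibitor controls, at 0.607 and 0.589, apart from the inhibitor libraries, at -0.108 and -0.138. On it the siRNA libraries, at -0.358 and -0.269, lay on the same side of the siRNA controls, at -0.181 and -0.142. Whatever set the inhibitor controls apart, such as a library preparation, could therefore also add to the correlation of the fold changes. This was not tested.

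Neighbouring genes moved together in both comparisons. Before the correction, the difference between the 2 siRNA control libraries alone gave rho = 0.091, as large as the 0.089 of the siRNA comparison. That background was not computed with the correction. With the inhibitor a trend with GC content or length may account for it, since the rho of neighbours was 0.000 with the correction (permutation p = 0.907). With the siRNA such a trend is argued against as the whole source, as rho stayed at 0.044 over 9648 pairs (permutation p = 0.0002). Noise of single libraries is argued against as the whole source too, since the corrected fold of a gene from 1 pair of libraries correlated with that of its neighbour from the other pair at 0.028 (permutation p = 0.0008) and, with the pairs formed the other way, at 0.024 (permutation p = 0.0028). A change along chromosomes after loss of G9a stays a hypothesis, and a handling difference between siRNA and control cultures was not tested.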
